A study of Onthophagus taurus and Onthophagus nigriventris with 71 samples.

How the data were processed

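Gene expression was measured on custom 2-colour microarrays of the horned beetle Onthophagus taurus, each array comparing 2 RNA pools labelled with Cy5 and Cy3. Each pool held tissue from 4 individuals, per the labels, taken from pupae within 24 h of pupation. RNA was extracted with a column kit, amplified by in vitro transcription and coupled to the dyes, per the labels' protocols. The values used were 1 log ratio per probe and array, for 3840 probes and 71 arrays, with 0 missing values. The probes carry the names of 40 plates of 96 wells.

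The authors deposited these values as normalised log ratios, taken here as log2 because the submitters' processing notes name limma, whose log ratios are in that base. The background correction, the within-array normalisation and the limma version are not given in the sources used here. Array medians ran from -0.17 to 0.17. The numerator of the ratio is not stated either. The dyes were swapped within every group, with the focal tissue in Cy5 on 37 arrays and in Cy3 on 34. The plan had been to turn the ratios of one dye orientation, but 81 of 82 pairs of arrays of opposite orientation within a group correlated above 0. The ratios had therefore already been turned one way, and they were not turned again. Which way is open. The wording of the design, which sets each focal tissue relative to its comparison tissue, makes focal over comparison the likely direction, and a positive value then means higher in the focal tissue. Against treating this as settled, at least 99.1% of the values were printed with more than 6 significant digits on every array with focal RNA in Cy5, and 0% on every array with focal RNA in Cy3, so the 2 orientations had been handled separately. Values are therefore reported as positive or negative. If the direction were the other way, every sign would turn, and counts, sizes and correlations would stay.

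Probe identifiers were looked up in a table of 16956 O. taurus genes of the IU_Otau_3.0 assembly, and 0 of the 3840 matched. Probes are given by their identifiers, the planned lists of genes were not run, and several probes may report the same gene. The comparisons, the rule for named probes and the alternatives not named as later choices were fixed before the data were examined. Among probes past the threshold, with the same sign in all group means or with group ranges that did not overlap, the 2 largest positive and the 2 largest negative values were named. Where fewer than 5 probes passed, those with the smallest p were named.

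Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over the 3840 probes and a threshold of 0.05. The 48 O. taurus arrays of a focal against a comparison tissue formed 12 groups of 4 and were fitted together, so that all groups shared one estimate of the spread. The 4 arrays that hybridised large against small male head directly were fitted alone, as were the 19 arrays of O. nigriventris. The species were compared in a fit of their 31 thorax arrays. Each fit held a dye term per probe, which both species shared in the thorax fit. Large minus small male was the morph contrast, female minus the mean of both male groups the sex contrast, and an F test over head, thorax and legs tested whether the morph contrast differed between tissues. The spread of a contrast was the square root of its variance across probes less the mean squared standard error. Correlations across probes are descriptions, since probes are not independent replicates. Values with no effect were obtained from 20 simulations with the noise of the real arrays, including the correlation of same-numbered arrays across epidermal tissues. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

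The fits were tested on simulated data with the noise of the real arrays. For the morph contrast in the head over 3840 probes, 25.4% of probes changed by 0.5 on the log2 scale were recovered, 77.6% of those changed by 1 and 98.5% of those changed by 2. For the direct arrays these shares were 1.49%, 46.3% and 89.4%. For the morph contrast of O. nigriventris they were 0%, 26.9% and 83.3%. Simulations of these comparisons without any change gave 0 calls. Their noise was drawn independently for each probe and array. The real arrays may carry more structure, since a regrouping of leg arrays gave 117 calls where the real legs morph contrast gave 0. The shares and the 0 calls therefore need not hold for the real arrays. The number of arrays limits the precision.

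No pair of arrays was identical, the highest correlation being 0.950. The labels number the arrays of each group but do not say whether a number marks the same animals, so no pairing was used. The arrays of a group are separate pools by their labels, without a statement that the animals came from separate rearings, so p-values measure the spread between these pools. The alternatives tried were centring of each array, scaling of each array to one spread, no dye term, fits of only the groups compared, array weights, robust empirical Bayes, replicate blocks, and leaving out each array in turn. Choices added after seeing the data are named as such.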

Results

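The arrays compared the developing epidermis of head, prothorax and legs with that of the dorsal abdomen, and the brain with ganglia, in pupae of Onthophagus taurus. Males of this beetle follow one of 2 developmental paths: large males grow head horns and fight, whereas small males remain hornless and sneak matings. Each of the 4 tissues was measured in females, large males and small males with 4 arrays per group, giving 48 arrays. A further 4 arrays hybridised the head epidermis of large males directly against that of small males. For O. nigriventris, a species whose horns grow from the thorax, thorax was compared with abdomen on 19 arrays, 7 of females, 5 of large males and 7 of small males. Within the O. taurus groups of head, thorax and legs, arrays correlated with a lowest r of 0.734 and a highest of 0.950 across probes. In the brain groups the lowest r was 0.105, between small male arrays. In the O. nigriventris groups it was -0.037, and arrays of the same dye orientation correlated more closely there (mean r 0.450 to 0.532) than arrays of opposite orientation (0.150 to 0.167).

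The first question was which transcripts distinguish outgrowing tissues from abdominal epidermis. In the head, averaged over females and both male morphs, 2898 of 3840 probes passed limma's test, 1607 positive and 1291 negative. OtP015-B09 had the largest positive value, 5.14 ± 0.17 on the log2 scale (SE, 12 arrays), followed by OtP008-B09 at 4.88 ± 0.19. OtP001-H03 at -5.34 ± 0.18 and OtL005-F06 at -5.15 ± 0.18 were the largest negative values. In the thorax 2569 probes passed, 1399 positive and 1170 negative, led by OtP008-D05 at 4.85 ± 0.23 and OtL009-F10 at 4.57 ± 0.31, and by OtL006-A08 at -5.24 ± 0.18 and OtL013-C03 at -4.82 ± 0.17. In the legs 2595 passed, 1438 positive and 1157 negative. OtL009-F10 led there too with 5.33 ± 0.31, and OtP013-D03 followed with 4.98 ± 0.30. OtL011-A04 stood at -5.22 ± 0.20 and OtL002-A12 at -5.17 ± 0.22. Over 2-fold changes were called for 647 probes in the head, 455 in the thorax and 586 in the legs.

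The 3 epidermal tissues shared much of their difference from the abdomen. In all 3, 1013 probes were positive and 815 negative, where independent lists would share 219.2 and 118.5. Only 218 probes were called with opposite signs in any pair of these tissues. The tissue effects correlated across probes with r of 0.889 for head and thorax, 0.825 for head and legs and 0.857 for thorax and legs. Simulated arrays without any effect gave 0.303, 0.310 and 0.299, because same-numbered arrays deviated together. The corresponding covariances were 0.705, 0.728 and 0.613 against a simulated 0.0035, 0.0035 and 0.0034. All 3 tissues were set against abdominal epidermis, so part of the overlap belongs to that tissue. The abdomen cancels in differences between the tissues. Head and thorax then differed at 1177 probes, head and legs at 1827, and thorax and legs at 873.

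The brain was compared with ganglia. Here 1989 probes passed, and the ratios were smaller, with an SD across probes of 0.517 against 0.990 in the head. OtL010-F09 at 3.37 ± 0.17 and OtP004-F09 at 3.34 ± 0.17 were the largest positive values (SE, 12 arrays). OtP006-B04 at -3.67 ± 0.11 was the largest negative value. OtP008-D05, the leading positive probe of the thorax, was negative in the brain at -2.91 ± 0.23. As deposited, 770 brain calls were positive and 1219 negative, and 945 and 956 after each array was centred on its median, which evens the signs by construction.

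The central question of the design was how far the male morphs differ, and in which tissues. In the head, large and small males differed at 284 probes, 133 positive and 151 negative, and 130 of them differed over 2-fold. OtL002-E05 showed the largest difference, 4.26 ± 0.22 (SE, limma adjusted p = 4.68e-18). Every large male array lay above every small male array, which the rule for named probes required. Its log ratio was 4.92 ± 0.30 in large male heads (SD, n = 4), 0.66 ± 0.53 in small male heads (SD, n = 4) and 0.27 ± 0.34 in female heads (SD, n = 4). OtL006-A04 differed by 3.57 ± 0.32, with 3.30 ± 0.55 in large males, -0.27 ± 0.65 in small males and -0.10 ± 0.34 in females (SD, n = 4 each). The largest negative differences were -2.18 ± 0.44 for OtL017-E05 and -2.05 ± 0.41 for OtP020-G02. The latter stood at -3.67 ± 0.29 in large males, -1.62 ± 0.31 in small males and -1.09 ± 0.58 in females. OtL017-E05 followed another order, with -4.67 ± 0.69 in large males, -2.49 ± 0.65 in small males and -4.41 ± 0.10 in females. With each array scaled to one spread, 78 probes passed, 57 positive and 21 negative, all 78 among the 284, and OtL017-E05 and OtP020-G02 no longer passed. Fitting only the 8 male head arrays gave 111.

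**Figure D1:**
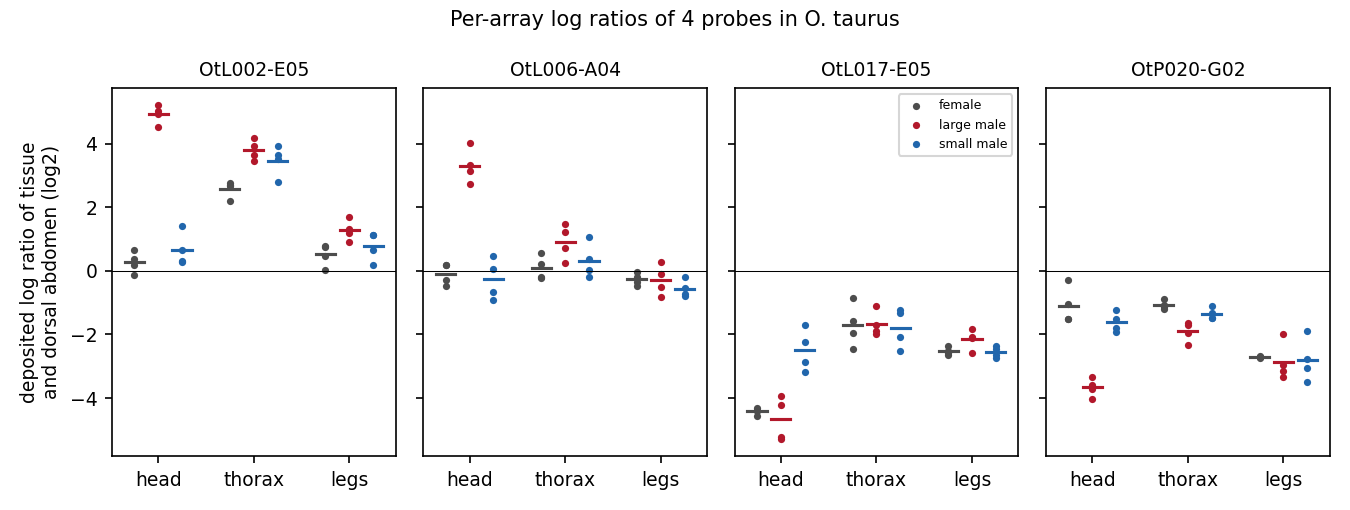
Log ratios on the log2 scale of the 4 probes named for the morph difference in the head, one point per array and a bar at the mean of 4 arrays, for females, large males and small males in 3 epidermal tissues of O. taurus. OtL002-E05 averages 4.92 in large male heads and 0.66 in small male heads, whereas in the thorax large and small males differ by 0.34.

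In the other tissues few probes separated the morphs. The thorax had 1 call, OtP010-D09 at 1.41 ± 0.24 (SE, limma adjusted p = 0.00371). It lost significance when only the 8 arrays compared were fitted. Scaled arrays gave 6 calls, no dye term 2 and array weights 13. The thorax count was 0 without large male replicate 1, large male 4 or small male 1, which ends the call of OtP010-D09, and it was 3 without large male 2, 2 without small male 3 and 6 without small male 4. OtP013-C07 came next at 1.17 ± 0.25 with an adjusted p of 0.0539, and passed without large male 2, small male 3 or small male 4. In the legs limma gave 0 calls, with 235 probes at an unadjusted p under 0.05 where 192 are expected by chance. Without large male leg replicate 4, small male 1 or small male 4 there was 1 call, and array weights gave 8. In the brain OtP020-H12 was the single call at 1.43 ± 0.27 (adjusted p = 0.0237). There 101 probes had an unadjusted p under 0.05, fewer than the 192 expected by chance. The narrow brain arrays shared their estimate of the spread with the epidermal arrays, so the test may be too strict in the brain. OtP020-H12 was lost without the dye term, with only the groups compared and with array weights, which gave 1 other call. It was also lost without large male 1, large male 4, small male 3 or small male 4. Scaled arrays gave 22 calls, 8 positive and 14 negative. The brain count was 0 without large male replicate 1, large male 4 or small male 4, and 11 without large male 2, 5 without large male 3, 12 without small male 1 and 4 without small male 3. Both OtP010-D09 and OtP013-C07 also differed in the head, by 1.70 ± 0.24 and 1.90 ± 0.25. The difference of the morph contrast between head, thorax and legs was tested directly and passed at 42 probes. In 40 of these the head was farthest from the other tissues, and all 42 were also called in the head. OtL002-E05 led this test with an adjusted p of 1.24e-12, its contrast being 0.34 ± 0.22 in the thorax and 0.50 ± 0.22 in the legs. Some of the 42 had nearly the same contrasts in head, thorax and legs, such as OtL013-G05 (3.27, 0.96 and 0.36) and OtL020-D11 (3.25, 1.04 and 0.43). Whether such probes report the same gene was not tested, so the 42 need not be separate genes. The count of 42 fell to 3 with arrays scaled to one spread, and to 26 without large male head replicate 3.

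Across all probes, the morph contrasts of head and thorax correlated with r = 0.424 and a covariance of 0.0558, where simulated arrays without effect gave 0.302 and 0.0204. Head and legs gave 0.129 and 0.0157 against a simulated 0.307 and 0.0208. Thorax and legs gave 0.251 and 0.0166 against 0.308 and 0.0207. The simulation put a single correlation, pooled over the tissue pairs, into every pair, so its r follows from that input. It is not matched to each pair, and both pairs with legs fell below it. When the tissues were taken from arrays of different numbers, over the 6 ways of halving them, mean r was 0.183 for head and thorax (range 0.0834 to 0.277). It was 0.0004 for head and legs (range -0.138 to 0.0593) and 0.0204 for thorax and legs (range -0.112 to 0.108).

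The direct arrays were run to check the head morph differences. They called 9 probes, all positive, and 694 had an unadjusted p under 0.05. OtL002-E05 stood at 4.43 ± 0.20 and OtL006-A04 at 3.43 ± 0.22 (SE, limma, 4 arrays), close to 4.26 and 3.57 on the arrays against abdomen. All 9 calls were among the 284. Of the 284, 282 had the same sign on the direct arrays and 170 had an unadjusted p under 0.05. Across probes the 2 estimates correlated with r = 0.793 (rho = 0.648) and a slope of 0.813. The direct contrast correlated with the thorax morph contrast with r of 0.329, with the legs at 0.0037 and with the brain at -0.155. The count of 9 rested on single arrays. It was 15 without direct replicate 1, 137 without replicate 2, 0 without replicate 3 and 44 with no dye term. OtL002-E05 lost its call without replicate 3, and OtL006-A04 without replicate 1 or 3. Without direct replicate 4 the correlation with the indirect estimates was 0.605.

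**Figure D2:**
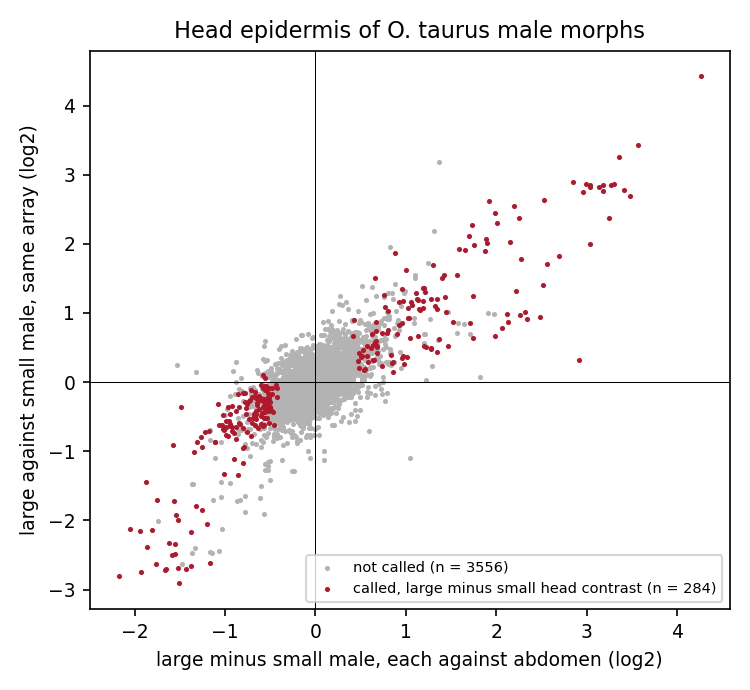
Large against small male head epidermis, on the x axis as the difference of log2 ratios to abdomen (8 arrays) and on the y axis as the log2 ratio on the 4 direct arrays, one point per probe. Red points are the 284 probes called on the arrays against abdomen, and 282 of them have the same sign on both axes (r = 0.793 over all probes).

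The design also asked whether the morphs differ as much as the sexes. Contrasts between groups, of morphs as of sexes, are of ratios to abdomen, or to ganglia for the brain. A difference can therefore come from either tissue, and the direct arrays check this probe by probe only for large against small male heads. A difference in the abdomen alone would enter head, thorax and legs alike. The spread of female minus large male was 0.437 in the head (0.425 to 0.463 with single arrays left out). In the legs it was 0.153 (0.057 to 0.205). This argues against the abdomen as the whole cause for female minus large male in the head, but not as a part of it. Females differed from the mean of the males at 98 probes in the head, 38 positive and 60 negative. The largest negative values were -1.62 ± 0.23 for OtP005-F04 and -1.58 ± 0.15 for OtP003-H05 (SE, 12 arrays). Both also passed for large minus small male heads, at 1.30 ± 0.26 and 1.92 ± 0.18 (SE). Neither was called between female and small male heads, so their sex contrasts rest in part on large males. OtP008-G10 at 1.20 ± 0.26 and OtP002-C10 at 1.19 ± 0.30 led the positive values, and in both, large male head replicate 4 lay far below the other large male arrays, at -2.70 and -3.29. In the thorax 81 probes passed, 36 positive and 45 negative. OtL018-C11 stood at -1.86 ± 0.48 and OtP005-E03 at -1.82 ± 0.38, with OtL001-B12 at 0.80 ± 0.20 and OtP002-D03 at 0.72 ± 0.19 on the positive side. The legs had 8 calls, 7 of them negative, among them OtP013-H01 at -1.62 ± 0.28 and OtP019-H01 at -1.17 ± 0.25, and OtP019-B06 was positive at 0.54 ± 0.11. The brain had 0 calls in limma, with 113 probes at an unadjusted p under 0.05 where 192 are expected by chance. The head count was 59 without female head replicate 1, 47 without female head replicate 4, 8, all negative, with arrays scaled to one spread and 35 when only the head arrays were fitted. OtP008-G10 and OtP002-C10 passed in neither of these last settings, and OtP002-C10 was also lost without female replicate 2, female 4 or small male 1. Centred arrays gave 21 positive and 65 negative. The thorax count was 39, 13 and 50 without female replicates 1, 2 and 4. It was 28, 52 and 35 without large male replicates 1, 2 and 4, and 34 and 32 without small male replicates 1 and 3. Scaled arrays gave 16 (6 positive, 10 negative), centred arrays 32 positive and 58 negative, and array weights 229. All 4 named thorax probes lost their call with scaled arrays, and OtP002-D03 also with no dye term. Of the 12 arrays, leaving out any of 11 ended the call of OtP002-D03, any of 6 that of OtL001-B12, any of 6 that of OtL018-C11, and female replicate 2 that of OtP005-E03. The leg count was 15, 1, 0 and 0 without female replicates 1, 2, 3 and 4, 14 and 1 without large male replicates 2 and 4, and 29, 4, 1 and 1 without small male replicates 1, 2, 3 and 4. It was 0 with scaled arrays or only the groups compared, and 186 with array weights. OtP013-H01 was lost without female replicate 3 or 4, and OtP019-B06 and OtP019-H01 each without any of 6 arrays. The brain gave 9 calls without female replicate 1 and 2 without small male replicate 2.

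In ratios to abdomen, female heads differed from those of large males at 369 probes, 188 positive and 181 negative. From those of small males they differed at 1 probe, OtP011-A05 at -0.74 ± 0.14. The count against small males was 3, 5, 0 and 0 without female replicates 1, 2, 3 and 4, and 0 and 6 without small male replicates 1 and 4. OtP011-A05 was lost with scaled arrays, with only the groups compared, and without female replicate 3, female 4, small male 1 or small male 2. Centring, array weights and the replicate blocks each gave 3 calls. With 8 arrays each, these comparisons have the precision of the morph contrast. OtP020-G02 at 2.58 ± 0.41 and OtP003-F11 at 2.31 ± 0.53 were the largest positive values of female minus large male, and OtL002-E05 at -4.65 ± 0.22 and OtL006-A04 at -3.40 ± 0.32 the largest negative ones. After centring, the split was 132 positive and 214 negative. With scaled arrays 103 probes passed, 29 positive and 74 negative, without OtP003-F11. With only the groups compared 148 passed. In the thorax 107 probes separated females from large males, 45 positive and 62 negative, and 0 separated females from small males (409 at an unadjusted p under 0.05, limma). OtP005-E03 at -2.51 ± 0.44 and OtP004-A07 at -2.23 ± 0.59 led the negative values, and OtP005-C05 at 1.65 ± 0.45 and OtL007-H04 at 1.13 ± 0.23 the positive ones. The thorax count was 5 without large male replicate 4, 12 without female replicate 2, 27 without large male replicate 1, 54 without large male replicate 2 and 56 without female replicate 1. It was 58 (30 positive, 28 negative) with scaled arrays, 111 (39 positive, 72 negative) with centred arrays and 472 with array weights. OtP005-C05 was lost with scaled arrays and without any of 7 of the 8 arrays. OtP004-A07 was lost with only the groups compared and without any of 6 arrays, and OtL007-H04 with only the groups compared and without female replicate 2. In the legs female minus large male gave 1 call, OtP013-H01 at -1.85 ± 0.32, and female minus small male 0 (408 at an unadjusted p under 0.05). The first count was 3, 0 and 0 without female replicates 1, 3 and 4, and 3 and 2 without large male replicates 1 and 4. It was 0 with scaled arrays or only the groups compared, which ends the call of OtP013-H01, as does leaving out female replicate 3 or 4, and 110 with array weights. The second was 1 without female replicate 1, 21 without small male replicate 1, 2 with the replicate number as a factor and 93 with array weights. In the brain both gave 0 in limma, with 124 and 113 at an unadjusted p under 0.05 where 192 are expected by chance. With scaled arrays they gave 10 (6 positive, 4 negative) and 1. Without female brain replicate 1 they gave 4 and 2, and without small male brain replicate 2 the second gave 2.

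A measure without a threshold was computed as well. The spread of large minus small across probes, beyond the standard error, was 0.418 in the head (range 0.400 to 0.433 with single arrays left out), 0.060 in the thorax (0 to 0.114), 0 in the legs (0 to 0.104) and 0 in the brain (0 to 0.180). Female minus large male gave 0.437 in the head (0.425 to 0.463), 0.303 in the thorax (0.277 to 0.320), 0.153 in the legs (0.057 to 0.205) and 0 in the brain (0 to 0.103). Female minus small male gave 0.149 in the head (0.113 to 0.193), 0.174 in the thorax (0.127 to 0.217), 0.162 in the legs (0.055 to 0.249) and 0 in the brain (0 to 0.142). In the legs, female minus large male was 0.057 without female replicate 3, and female minus small male was 0.055 without small male replicate 3, 0.103 without female replicate 3 and 0.249 without small male replicate 1. For the morph contrast, the thorax value was 0 without large male replicate 1, large male 4 or small male 2, 0.114 without small male 3 and 0.106 without small male 4. The legs value was 0.104 without large male replicate 1, 0.016 without large male 2, 0.057 without large male 4 and 0.087 without small male 4. The standard error subtracted was shared with the other tissues, so a 0 in the brain does not show the absence of a difference. In the brain only small male replicate 1 and female replicate 1 moved a value from 0. Without the former, the morph contrast gave 0.180 and female minus small male 0.142, and without the latter, female minus large male gave 0.103 and female minus small male 0.082. With scaled arrays large minus small gave 0.298 in the head, 0.052 in the thorax, 0 in the legs and 0.267 in the brain, so that the brain came close to the head. Female minus large male then gave 0.324, 0.331, 0 and 0.122, and female minus small male 0, 0.190, 0.064 and 0.118. In ratios to abdomen, female heads lay farther from large than from small males, with mean squared differences of 0.259 and 0.0902. The exact two-sided permutation test over the 70 assignments of male arrays gave p = 0.0286, the smallest it can give, and 0.143 after adjustment over 5 comparisons. The thorax gave 0.160 and 0.0984 (exact permutation p = 0.114, adjusted 0.286). Legs (0.0913 and 0.0941) and brain (0.0528 and 0.0541) did not show this order, with exact permutation p of 0.886 and 0.971. O. nigriventris gave 0.177 and 0.126 (exact permutation p = 0.413). Across probes, the morph contrast and the sex contrast correlated with r = -0.508 in the head and -0.344 in the thorax, against -0.015 and -0.0004 in simulations without effect. With single arrays left out, r ran from -0.528 to -0.405 in the head and from -0.408 to -0.161 in the thorax, where small male replicate 4 gave the -0.161. In the legs (0.020, range -0.170 to 0.286) and the brain (0.014, range -0.114 to 0.314, rho = -0.117) the sign changed with the array left out. Covariances were -0.0844 in the head and -0.0307 in the thorax, against a simulated -0.0009 and 0.

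**Figure D3:**
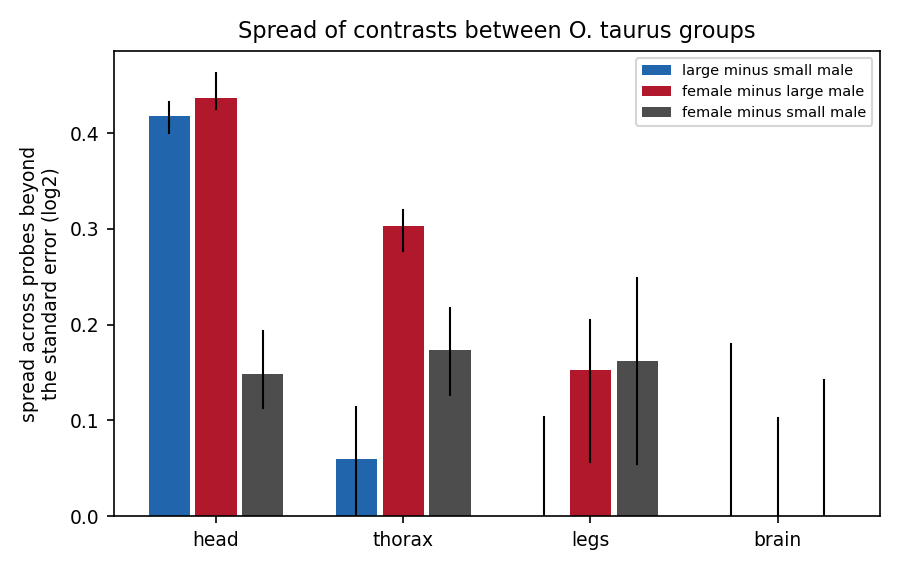
Spread across probes on the log2 scale, beyond the standard error, of 3 contrasts between groups of 4 arrays in each O. taurus tissue. Lines show the range with single arrays left out. In the head, large minus small male (0.418) and female minus large male (0.437) exceed female minus small male (0.149). The brain values of 0 hold for arrays as deposited, and large minus small is 0.267 there with scaled arrays.

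In O. nigriventris 987 probes differed between thorax and abdomen, 519 positive and 468 negative. OtL016-H05 at 4.40 ± 0.32 and OtP008-D05 at 4.34 ± 0.27 were the largest positive values (SE, 19 arrays), the latter also the leading thorax probe of O. taurus. OtL015-C02 at -3.68 ± 0.18 and OtL004-F05 at -3.62 ± 0.14 were the largest negative ones. The morph contrast gave 0 calls (266 at an unadjusted p under 0.05, limma), as did the sex contrast (145). The smallest p of the morph contrast belonged to OtP013-C07, at 2.40 ± 0.47 with an adjusted p of 0.176. Its log ratio was 3.66 ± 1.5 in large males (SD, n = 5), 1.24 ± 0.92 in small males (SD, n = 7) and 0.87 ± 0.56 in females (SD, n = 7). It passed, as the single call, with the replicate number as a factor. Without large male replicate 4 the morph contrast also gave 1 call. The morph and sex contrasts correlated with r = -0.181 across probes, against a simulated -0.096, and ran from -0.293 without large male replicate 1 to -0.062 without small male replicate 1, a range that includes the simulated value. The dye term was called at 863 probes in this species, 648 positive and 215 negative, compared with 133 in O. taurus.

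Thorax effects of the species correlated across probes with r = 0.729 (rho = 0.593), with a slope of 0.513 for O. nigriventris on O. taurus. Both species called 870 probes, 829 of them with the same sign. Of these 433 were positive and 396 negative, where independent lists would share 189.1 and 142.6. The difference between the species passed at 697 probes, 382 positive and 315 negative for O. nigriventris minus O. taurus. After each array was centred on its median 706 passed, 440 positive and 266 negative, and array weights gave 1107. OtL006-H03 at 4.41 ± 0.43 and OtL010-D10 at 4.27 ± 0.24 were the largest positive differences, and OtL009-F10 at -4.76 ± 0.35 and OtP013-D03 at -4.69 ± 0.23 the largest negative ones. In 585 of the 697 the effect was smaller in O. nigriventris, and in 298 the effects had opposite signs. With arrays scaled to one spread 1319 probes passed, and 1221 of these were smaller in O. nigriventris. The probes were designed for O. taurus, so a smaller ratio can also come from weaker hybridisation. The fit used the same dye term and the same spread for both species, although their dye terms correlated with r = 0.059. More O. nigriventris arrays had focal RNA in Cy5 than in Cy3, so dye bias can enter the difference. With no dye term 646 probes passed, 642 of them among the 697.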

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

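Of the tests of technical explanations here, those of abdominal tissue, of wider ratios as the whole cause, of scaling without brain arrays, of unturned arrays, of the O. nigriventris assignments and of a difference common to all tissues were chosen only after the result was seen, as were the adjustment over tissues and the bound of 2 SE. The effect of morph differed between head, thorax and legs at 42 probes, and the thorax effect differed between the species at 697. The tissue effects themselves differed between head and thorax at 1177 probes, head and legs at 1827 and thorax and legs at 873. In 4 of 32 sets of array summaries 1 array lay far from its group, where chance marks about 1 in 20. The SD of log ratios was 0.610 on O. nigriventris female replicate 3 (others 0.863 to 1.03), 0.494 on O. nigriventris small male replicate 4 (others 0.934 to 1.19) and 0.391 on large male brain replicate 3 (others 0.594 to 0.627). Large male head replicate 4 had a mean correlation of 0.839 with its group (others 0.901 to 0.909). Among 141 sets of values of named probes 7 had such an array, about as many as chance gives. OtL009-F10 read 6.55 on small male legs replicate 3 and -2.20 on O. nigriventris female replicate 7. OtL010-F09 read 2.16 on large male brain replicate 3, OtP004-F09 2.02 on small male brain replicate 3, and OtP013-D03 4.02 on large male thorax replicate 4. OtP008-G10 and OtP002-C10 read -2.70 and -3.29 on large male head replicate 4.

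Regrouping the arrays tested whether chance groupings give as many calls. For the tissue effects, 1 of 100 sign patterns, the real one, gave as many calls. This held in head (2898, highest other 2414), thorax (2569, highest other 2087), legs (2595, highest other 2330) and brain (1989, highest other 1273), and in O. nigriventris (987, highest other 330). It held too for the thorax sex contrast (1 of 100, 81 against 4) and the species difference (1 of 100, 697 against 23). A share of 1 in 100 is the smallest such a draw can give. Unadjusted, it argues against chance without excluding it. Among 35 splits only the real one gave as many calls for the head morph contrast (284 against 81) and the morph by tissue test (42 against 12). The same held for female minus large male in head (369 against 114) and thorax (107 against 2). A share of 1 in 35 is the smallest those splits can give, and unadjusted it argues against chance without excluding it. For the head sex contrast 3 of 100 splits gave as many (98, highest other 192), a share under 0.05 but too close to it in a draw of 100 from 495 splits to exclude chance. The split with 192 calls joined large male 1, 2 and 4 with small male 4, so it comes near to the morph contrast. Splits that part the morphs carry their difference at 284 probes, so this regrouping cannot decide on chance for the head sex contrast. None of these shares was adjusted over the regroupings. Chance cannot be excluded for the morph contrasts of thorax (8 of 35 splits, 1 against 4) and brain (8 of 35, 1 against 19), the sex contrast of legs (9 of 100, 8 against 41), female minus small male in head (12 of 35, 1 against 53) and female minus large male in legs (4 of 35, 1 against 4). Where the real count is 0 every split gives as many by construction (35 of 35 or 100 of 100), so regrouping tests nothing. This holds for the legs morph contrast (highest other 117), the brain sex contrast (45), female minus small male in thorax (12), legs (10) and brain (60), female minus large male in brain (43), and the O. nigriventris morph (2) and sex contrasts (1). The 117 calls of one split of leg arrays, large male 1 and 2 with small male 1 and 4 against the rest, point to a structure of those arrays, but as the highest of 35 splits this was not tested against noise. For the direct arrays 8 sign patterns are too few for a share under 0.05 (9, highest other 0).

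The first pattern weighed is that morph calls lie mostly in the head. A difference in the abdominal epidermis would not appear on the direct arrays, yet over the 284 probes the slope of direct on indirect values was 0.874 (0.685 to 1.06 with single direct arrays left out), which argues against it and, since ratios to abdomen play no part there, also against wider ratios on the large male head arrays as the whole cause. A single deviating large male array is argued against as well, since at least 219 probes passed whichever of the 4 was left out. Whether wider ratios added part of the calls cannot be told apart. Scaling all arrays to one spread left 78 calls, between the values set in advance for either reading, and 132 with the narrow brain arrays also left out. The scaling cannot decide this. The median absolute deviation it evens out averaged 0.665 on large male, 0.638 on small male and 0.711 on female head arrays. Among large male head arrays only replicate 4, at 0.925, was wide by this measure. By SD large male head arrays were wider, at 1.09 to 1.29 against 0.916 to 1.08 in small males. On the direct arrays 282 of the 284 probes kept their sign, so a difference between large and small male heads goes with both kinds of array. What share of the 284 calls wider ratios added stays open.

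The second pattern is that O. nigriventris arrays correlate by dye orientation. A dye bias of the probes that both species share is argued against, since the dye terms of the species correlated with r = 0.059. Arrays of one orientation left unturned are argued against too, as the mean of either orientation correlated with the O. taurus thorax effect, at 0.589 and 0.571. A bias of orientation particular to these hybridisations goes with the dye term, called at 863 probes here against 133 in O. taurus. Array medians of O. nigriventris also followed orientation, from -0.166 to -0.0375 with focal RNA in Cy3 and from 0.0167 to 0.166 in Cy5. Whether the dyes or the separate handling of the orientations caused it stays open. The design gives no biological explanation, and none was tested.

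The third pattern is that the O. nigriventris thorax morph contrast ran with the O. taurus head morph contrast across probes (r = 0.208). The exact two-sided permutation p over 792 assignments was 0.0354 for the head and 0.0391 for the O. taurus thorax (r = 0.097), each 0.0782 after adjustment over 4 tissues. The test had been stated on the unadjusted p, which passes, and was moved to the adjusted one once both were seen because the head was 1 of 4 tissues looked at, so chance stays open. Amplitude along the tissue effect stays open, since the residual correlation after regression on the female effects, 0.167, passed the 0.1 stated in advance but lay less than 2 jackknife SE (0.072) above the 0.05 that amplitude allows. A morph difference common to the O. taurus tissues stays open too. The r with the head exceeded that with the thorax by 0.111 (0.046 to 0.133 with single arrays left out), less than 2 SE (0.094). With the legs r was 0.015 (jackknife SE 0.07) and with the brain -0.045, so no sharing was seen there. A shared horn-related difference may contribute, as a hypothesis that chance leaves open.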

How the results depend on the processing

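The fits without brain arrays, without the brain arrays numbered 3, without the male head arrays numbered 4 and without the array least like its group were chosen after seeing the data. Of 464 alternative values of 60 named probe values, 427 kept their side of the threshold, 29 lost significance, 8 gained it and 0 turned sign. With single arrays left out, 17 of the 60 lost significance at least once, 3 gained it and 0 turned sign. The tissue effects of all 4 tissues and the O. nigriventris tissue effect stayed within 1.5 times of their counts under every alternative run. So did the head morph contrast, except for scaling to one spread, with or without the brain arrays, and the fit of only the groups compared. Robust empirical Bayes moved no count by more than 1.5 times. No value was missing, so the alternatives with other probe filters moved nothing and were not run, nor were those on probes of one gene and on gene lists. Fitting only the groups compared is the same fit for the O. nigriventris tissue and sex effects and the species difference. Signal over background was not used here, so no limit from dim spots is given. Except where said, the cause of a change was not tested.

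With arrays scaled to one spread, the calls were 78 for the morph contrast in head, 6 in thorax and 22 in brain. The sex contrast gave 8 in head, 16 in thorax, 0 in legs and 4 in brain. Female minus large male gave 103 in head, 58 in thorax, 0 in legs and 10 in brain, and female minus small male 0 in head, 2 in thorax and 1 in brain. The morph by tissue test gave 3 and the species difference 1319. The spread was 0.298 for head morph, 0.324, 0 and 0 for female minus large male in head, female minus small male in head and female minus large male in legs, 0.267 for brain morph and 0.122 for female minus large male in brain. Scaling widens the narrow brain arrays that share the estimate of the spread. With brain arrays left out as well, scaled arrays gave 132 for head morph, 30 for head sex, 182 and 193 for female minus large male in head and thorax, and 3 for the morph by tissue test. Unscaled fits without brain arrays stayed within 1.5 times. Spreads trimmed to the 1st to 99th percentile of probes were 0.280 for head morph, 0.316 and 0 for female minus large and small male in head, 0 for thorax morph, 0.249 and 0.109 for female minus large and small male in thorax, and 0.071 and 0.078 in legs.

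Fitting only the groups compared, with fewer arrays to estimate the spread, gave 111 for head morph, 0 for thorax and brain morph, 35 for head sex, 0 for legs sex, 148 for female minus large male in head and 0 in legs, 0 for female minus small male in head, and 25 for the morph by tissue test. Without a dye term, thorax morph gave 2, brain morph 0 and the direct arrays 44. Array weights gave 13 for thorax morph, 8 for legs morph, 229, 186 and 1 for sex in thorax, legs and brain, and 472 and 110 for female minus large male in thorax and legs. They gave 3, 2 and 93 for female minus small male in head, thorax and legs, 78 for the morph by tissue test and 1107 for the species difference. Centring on the median gave 3 for female minus small male in head. With the array least like its group left out of every group, thorax morph gave 7, brain morph 0, brain sex 1, female minus small male 0 in head, 2 in legs and 1 in brain, and female minus large male 20 in thorax and 7 in brain. Without the brain arrays numbered 3 of both male morphs, brain morph gave 0.

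By the rule set, array numbers were not used to pair the samples, since the labels do not say that they mark the same animals. Residuals of same-numbered arrays of a sex or morph correlated across epidermal tissues with a mean r of 0.232, over 0.1 in 28 of 36 pairs. Arrays of other numbers gave a mean r of -0.077, over 0.1 in 13 of 108 pairs. The own number was highest in 57 of 72 cases. The data thus hint that same-numbered arrays are linked, and tests between tissues did not use this. With the replicate block as a factor, head morph gave 310, thorax morph 2, brain morph 4, female minus small male 3 in head and 2 in legs, and O. nigriventris morph 1. With a random replicate block head morph gave 287, female minus small male in head 3 and the morph by tissue test 51, against 42 without a block. In O. nigriventris and on the direct arrays no number recurs within a sex or morph, so the random block changes nothing there.

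With single arrays left out, calls ran from 0 to 6 for thorax morph, 0 to 1 for legs morph and 0 to 12 for brain morph. Head morph ran from 203 to 284. Sex ran from 47 to 116 in head, 13 to 99 in thorax, 0 to 29 in legs and 0 to 9 in brain. Female minus large male ran from 5 to 90 in thorax, 0 to 3 in legs and 0 to 4 in brain, and female minus small male from 0 to 6 in head, 0 to 21 in legs and 0 to 2 in brain. The direct arrays ran from 0 to 137, O. nigriventris morph from 0 to 1 and the morph by tissue test from 26 to 54. The spread ran from 0 to 0.180 for brain morph, 0 to 0.103 for female minus large male in brain and 0 to 0.142 for female minus small male in brain. The correlation of direct with indirect head values ran from 0.605 to 0.812.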

Other observations

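The position of females and the probes below were examined after the results were seen. In ratios to abdomen, female heads resembled small male heads at most of the probes that separated the male morphs. On a scale where small males are 0 and large males 1, the median position of females over the 284 probes was 0.1, with quartiles at -0.094 and 0.327, and 237 probes placed females nearer to small males. The probes were chosen on the same male arrays, so the position is a description of them. Of the 133 positive and 151 negative probes, 100 and 93 were also called between females and large males, in the opposite sense, where independent lists would share 6.3 and 7.4. Both comparisons hold the large male arrays, and their correlation was -0.821 where simulated arrays without effect gave -0.510. The covariance was -0.206 against a simulated -0.0349. In 211 of the 284 the log ratio was farther from 0 in large than in small males.

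OtP013-C07 recurred across contrasts of large with small males. It stood at 1.90 ± 0.25 in the head, 1.17 ± 0.25 in the thorax, 0.34 ± 0.25 in the legs and -0.13 ± 0.25 in the brain (SE, 8 arrays each), at 2.01 ± 0.14 on the direct arrays and at 2.40 ± 0.47 in the O. nigriventris thorax. It was singled out after its values were seen. Only the head and direct values passed limma's threshold, with adjusted p of 4.97e-07 and 0.0267. OtP010-D09 showed a like order, with 1.70 ± 0.24, 1.41 ± 0.24, 0.24 ± 0.24 and -0.31 ± 0.24 in the 4 tissues, 2.12 ± 0.16 on the direct arrays and 1.5 ± 0.38 in O. nigriventris, the last with an adjusted p of 0.431.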
